A study of Homo sapiens with 4 samples.

How the data were processed

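The data are 4 ribosome profiling libraries of HEK293T cells, 1 for each combination of siRNA (control or SRα) and IP (CBP80 or eIF4E), with groups taken from the sample titles. Per the submitters' processing notes, the authors used cutadapt, STAR 2.5.2b and HTSeq with the hg19 genome build. The annotation, the strand setting, and the filters were not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol and libraries were prepared with a stranded mRNA kit. These protocols do not describe nuclease digestion or footprint selection, so the length of the fragments counted is not known here, and overlapping or antisense genes and near-identical gene copies may share reads in ways that could not be checked. The values the authors deposited are raw counts per gene, whole numbers without normalization, for 57820 versioned Ensembl gene IDs, followed by 5 summary lines that name no gene.

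The summary lines were kept out of library sizes and tests. Records placed at more than 1 position made up 89.5% of all records in the control CBP80 library (exact 95% Clopper-Pearson interval 89.47 to 89.49), 89.3% in the control eIF4E library (89.28 to 89.30), 90.7% in the SRα siRNA CBP80 library (90.66 to 90.68) and 90.3% in the SRα siRNA eIF4E library (90.32 to 90.35). Records outside annotated features made up 3.38%, 3.16%, 2.97% and 3.04% in the same order, and ambiguous records 0.281%, 0.298%, 0.249% and 0.269%. Gene counts were 6.86%, 7.25%, 6.11% and 6.36% of all records. Each library listed 0 unaligned records, so these are shares of the listed records and not of all reads. Whether a read placed at several positions was counted once or several times is not stated. Records may therefore not be independent, and the intervals above may be too narrow. The 10 gene IDs with the most counts held 5.90%, 5.67%, 6.19% and 5.86% of the gene counts. The files held 0 columns of other samples. No pair of libraries agreed within sampling noise: the chi-square statistic per degree of freedom over measured genes was between 2.21, for the SRα siRNA pair, and 7.01.

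Library sizes were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (0.984, 1.03, 0.980 and 1.01 in the order above). Genes were measured when their mean count over the 4 libraries was at least 20, which kept 7703 gene IDs and between 97.0% and 97.3% of the gene counts, while 36204 gene IDs had no count in any library. Log2 ratios used a prior count of 0.5 per library. Each ratio of 2 libraries has an exact 95% Clopper-Pearson counting interval, and a gene was counted as higher or lower when it differed by at least 2-fold with an interval that excluded equality. With 1 library per group these ratios have no p-value. A count of 0 was read as up to 3 counts, which equals 1.77, 1.34, 2.16 and 1.99 CPM in the 4 libraries. Reads without molecular identifiers are not independent molecules, so intervals, floors and simulated draws cover counting error only. The chance values are from 1000 draws in which each gene's counts were shared between libraries in proportion to their sizes, with no effect of siRNA or IP. Overlaps of siRNA and IP calls were also computed within 10 equal groups of genes by mean count (Mantel-Haenszel odds ratio). For rules that use all 4 libraries at once, Poisson counts were drawn around those shares.

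An additive model with siRNA and IP as terms was fitted to the 4 libraries with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Its single residual degree of freedom is the interaction. The biological coefficient of variation was 5.18%, and edgeR set the prior degrees of freedom to infinity, so that every gene took the spread from the trend over genes, its own interaction did not enter its test, and a gene that moved in 1 arm could be called. Tested on simulated data with 7703 genes and 200 changed, the siRNA test recovered 46%, 87% and 99% of genes changed by 1.5-fold, 2-fold and 4-fold, with 4, 4 and 1 false calls. The IP test recovered 41%, 83% and 100%, with 1, 3 and 10 false calls. The simulated counts took the fitted coefficient of variation for every gene and held no interaction or batch. Their false calls therefore do not give the rate of false calls in the real libraries. The same model was fitted with DESeq2 1.42.0 as an alternative. Adjusted p was missing, after DESeq2's own filter, for 3435 genes in the siRNA test and 4928 in the IP test.

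The comparisons, the tests, the count minimum, the size rule and the alternatives were chosen before the data were examined. The alternatives were DESeq2 size factors, total counts, count minimums of 10 and 100, no count minimum, a prior count of 5, a 1.5-fold rule and DESeq2's Wald test. Leaving out the 5 IDs over 5 times higher in the SRα siRNA eIF4E library than in any other, thinning all libraries to the smallest total, and edgeR's robust fit were added after the data were seen.

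The rule for named genes, also set before the data were examined, took for each 2-library comparison and for the interaction the 8 highest and 8 lowest log2 ratios among named genes with a mean of at least 100 counts and a counting interval that excluded equality, for each additive test the 8 called genes with the largest rise and the 8 with the largest fall, members of preset gene lists, and SRα with other factors of SRP and cap binding. The deposited files do not pair their IDs with names, and the RefSeq gene table used here matched 0 of them. The text therefore prints the first 2 IDs that rose and the first 2 that fell in the additive siRNA test. The 33 preset gene lists, which hold 1151 symbols and include ER client proteins, cytosolic and nuclear proteins and markers of other cell types, and the check of the SRα transcript were not run for the same reason. The cell-cycle reference of scran 1.30.0, which lists Ensembl IDs, was used after the data were seen, with medians set against 10000 random lists of the same size matched on mean count.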

Results

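Ribosome profiling libraries were made from HEK293T cells, a human embryonic kidney line, after control siRNA or siRNA against SRα. SRα is a subunit of the receptor at the endoplasmic reticulum (ER) membrane that receives the signal recognition particle (SRP), which brings ribosomes making secreted and membrane proteins to the ER. From each culture condition, mRNA bound to CBP80 or to eIF4E was recovered by immunoprecipitation (IP). CBP80 is the large subunit of the nuclear cap-binding complex, which sits on the cap of newly made mRNA, and eIF4E is the cytoplasmic cap-binding initiation factor that takes its place. The 4 groups had 1 library each, so no value below has a replicate. Counts within genes were 1723128 in the control CBP80 library, 2181925 in the control eIF4E library, 1419110 in the SRα siRNA CBP80 library and 1495526 in the SRα siRNA eIF4E library. At least 1 count was assigned to 16399, 17288, 16004 and 16612 gene IDs in these libraries, in the same order. The 7703 gene IDs with a mean of at least 20 counts over the 4 libraries were measured, and their median mean count was 74. The files list Ensembl gene IDs without gene names, so most genes are described by their values. Which of these IDs are capped mRNAs was not checked. The SRα transcript was not matched to an ID here, so the genes that fell, including those printed below, may include the siRNA target itself. The labels' protocols name an mRNA library kit and do not describe footprint selection, and the matched mRNA sequencing was not analysed here, so the counts do not separate ribosome occupancy from the amount of an mRNA in the precipitate.

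The first question was how the reads recovered with CBP80 and with eIF4E differed between cells given control siRNA and SRα siRNA. In an additive model of siRNA and IP over the 4 libraries, 609 genes rose and 611 genes fell with SRα siRNA out of 7703 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p of at most 0.05). Of the genes that rose, 601 were higher in both IPs, and of those that fell, 606 were lower in both. The genes were called on the average of these ratios, so this agreement follows in part from how they were chosen. The genes that rose held 16.5% of the gene counts in the control CBP80 library and 16.3% in the control eIF4E library, against 21.2% and 20.6% in the SRα siRNA libraries. The genes that fell held 14.1% and 13.3% of the counts under control siRNA and 9.49% and 9.12% under SRα siRNA. Most of these changes were small. The median fitted log2 change was 0.47 among genes that rose and -0.58 among genes that fell, 391 and 315 of them changed by less than 1.5-fold, and 61 and 66 changed by at least 2-fold.

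ENSG00000182934.7 fell most among the called genes. It had 300 counts in the control CBP80 library and 408 in the control eIF4E library, against 30 and 39 under SRα siRNA. These correspond to 177 and 182 CPM (TMM-scaled) under control siRNA and to 21.6 and 25.8 under SRα siRNA. The level was 8.20-fold lower in the CBP80 IP (95% counting interval 5.62 to 12.4) and 7.05-fold lower in the eIF4E IP (5.07 to 10.1), and the edgeR adjusted p was 4.16e-72. The CBP80 and eIF4E levels of this gene were not separated by the IP term (edgeR adjusted p = 0.877). ENSG00000198899.2 also fell, from 314 and 260 counts under control siRNA to 66 and 57 under SRα siRNA in the CBP80 and eIF4E IPs. It was 3.90-fold lower in the CBP80 IP (2.98 to 5.17) and 3.07-fold lower in the eIF4E IP (2.30 to 4.17), with an edgeR adjusted p of 4.82e-33. This gene was also higher in the CBP80 than in the eIF4E IP by 0.59 on the fitted log2 scale (edgeR adjusted p = 0.00068). Its CBP80-to-eIF4E ratio was 1.59 (1.35 to 1.89) under control siRNA. Under SRα siRNA it was 1.26 (0.868 to 1.82), an interval that included equality.

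The gene IDs with the highest fitted rise, ENSG00000124818.10 and ENSG00000201532.1, were read in the SRα siRNA eIF4E library and hardly elsewhere. ENSG00000124818.10 had 966 counts there, 2 in the SRα siRNA CBP80 library and 0 in both control libraries. ENSG00000201532.1 had 850 counts there and 0 in the other libraries. Against the level that 3 counts would give in the control eIF4E library, they were 478-fold and 420-fold higher, and the lower ends of their exact 95% counting intervals were 388-fold and 341-fold. A further 3 gene IDs were read in all 4 libraries but stood over 5 times higher in that library than in any other, with 530, 197 and 102 counts there against at most 10, 19 and 13 elsewhere. The additive test called all 5 of them, although no rise was seen in the CBP80 IP beyond the 2 counts given, because the model drew their spread from all genes and not from their own. Without these 5 IDs the model called 1219 genes.

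**Figure D1:**
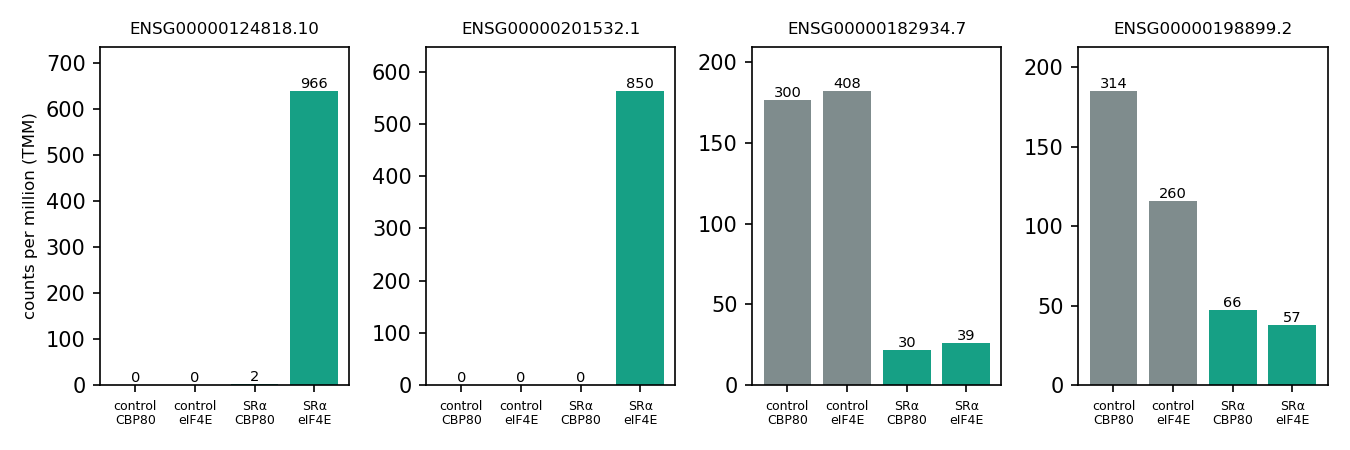
CPM (TMM-scaled) of the named gene IDs in each of the 4 libraries, control siRNA in grey and SRα siRNA in green, with the raw count above each bar and a separate y axis for each ID. ENSG00000124818.10 and ENSG00000201532.1 stand at 966 and 850 counts in 1 library, while ENSG00000182934.7 and ENSG00000198899.2 are lower in both SRα siRNA libraries.

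The model has 1 residual degree of freedom, the difference between the SRα effects in the 2 IPs. Because edgeR pooled this difference into a trend over genes, a p-value is not set against the gene's own spread. The labels do not say whether the IPs of 1 siRNA came from separate cultures, so the pooled spread may be technical. DESeq2's Wald test of the same model called 106 genes, all of them among the 1220 and in the same direction, and edgeR called 806 when genes with a mean of at least 10 counts were admitted, 751 when a mean of at least 100 was asked for and 749 when all libraries were thinned to the same total.

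Within the CBP80 IP alone, 107 genes were at least 2-fold higher and 135 at least 2-fold lower with SRα siRNA, with 95% counting intervals that excluded equality. Draws with no effect and the same depths gave 17.8 and 22.6 such genes on average and no more than 32 and 40. Within the eIF4E IP, 77 genes were higher and 86 lower, against 7.65 and 13.8 on average in the draws and no more than 18 and 29. Of the genes past this rule, 19 were higher in both IPs where independent lists would share 1.07, and 25 were lower in both where 1.51 would be shared. In the opposite direction, 1 gene was higher in the CBP80 IP and lower in the eIF4E IP, and 0 genes the other way round. These are ratios of 2 libraries with no replicate check, and the draws and intervals cover counting error only. The numbers and their balance depended on the count minimum. With no filter, 275 genes were higher and 210 lower in the CBP80 IP, and 229 and 205 in the eIF4E IP. With a mean of at least 100 counts they were 20 and 34, and 10 and 20.

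The SRα effects in the 2 IPs, which share no library, had a Pearson correlation of 0.433 and a Spearman correlation of 0.449 across the 7703 genes, which are not independent replicates. The highest Pearson correlation in the draws with no effect was 0.0503. The correlation was higher for the more abundant genes. Leaving out the 5 IDs, it was 0.2998 for the genes with the lowest mean counts (20 to 38.5) and 0.789 for those with the highest (170.5 and above). Among the 3064 genes with a mean of at least 100 counts, leaving out the 5 IDs, the log2 ratios spread with an SD of 0.35 in the CBP80 IP and 0.33 in the eIF4E IP, where counting error alone gave 0.15 and 0.14. Their Pearson correlation was 0.721, and the same 3064 genes had the same sign in both IPs in 74.8% of cases.

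**Figure D2:**
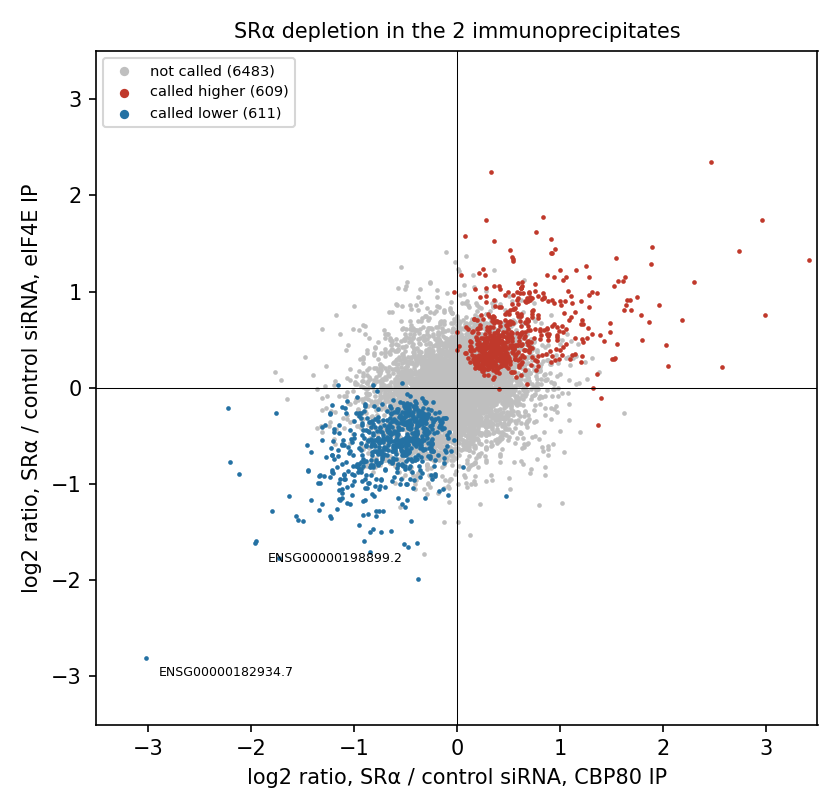
Log2 ratio of SRα to control siRNA in the CBP80 IP (x axis) against that in the eIF4E IP (y axis), with 1 point per measured gene, red for the 609 genes called higher by the additive model, blue for the 611 called lower and grey for the rest. Called genes lie mainly in the upper right and lower left, and 5 points, the IDs over 5 times higher in the SRα siRNA eIF4E library than in any other, lie beyond the axis limit of 3.5.

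The second question was which gene IDs were more abundant among ribosome profiling reads with CBP80 than with eIF4E. In the additive model, 185 genes were higher and 71 lower in the CBP80 than in the eIF4E IP (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p of at most 0.05). Of these, 183 were higher under both siRNAs and 64 were lower under both, which again follows in part from calling genes on the average. The CBP80-higher genes held 9.20% of the counts in the control CBP80 library and 6.74% in the control eIF4E library, and 7.31% and 6.05% in the SRα siRNA pair. The CBP80-lower genes held 1.33% and 1.93% in the control pair and 1.36% and 1.87% in the SRα siRNA pair. The median fitted log2 difference was 0.55 for CBP80-higher and -0.62 for CBP80-lower genes, and 21 and 11 genes differed by at least 2-fold. CBP80-higher genes were mostly abundant, with 124 of 185 among the 1926 genes with the highest mean counts, where 19 of the 71 CBP80-lower genes lay. The share of calls that were CBP80-higher was 72.3%, and it was 57.2% with scaling by total counts and 81.1% with DESeq2 size factors, which gave 107 and 36 CBP80-lower genes. DESeq2's Wald test called 32 genes in all, each of them among the 256, and edgeR called 137 genes with a mean of at least 10 counts admitted, 107 with at least 100 and 121 after thinning.

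Under control siRNA, 44 genes were at least 2-fold higher and 49 at least 2-fold lower with CBP80 than with eIF4E, against 7.32 and 11.5 on average in draws with no effect and no more than 17 and 23. Under SRα siRNA, 33 were higher and 54 lower. The draws for this pair gave 21.2 and 23.4 on average, so the number of higher genes lay above the upper end of the central 95% of the draws (30) and below the highest draw (35), and that of lower genes above the highest draw (41). The number of higher genes was 20 after thinning to equal totals and 16 with a prior count of 5. CBP80-lower genes numbered 49 in this pair without the 5 IDs. The siRNA conditions shared 7 CBP80-higher genes where independent lists would share 0.188, and 2 CBP80-lower genes where 0.344 would be shared. The number of CBP80-lower genes under control siRNA was 75 with scaling by total counts.

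The CBP80-to-eIF4E ratios under the 2 siRNAs had a Pearson correlation of 0.166 and a Spearman correlation of 0.195 across the 7703 genes, where the highest Pearson value in the draws was 0.0527. Without the 5 IDs the Pearson correlation was 0.207, and among the 3064 genes with a mean of at least 100 counts it was 0.421. For these abundant genes the SD of the log2 ratio was 0.26 under control siRNA and 0.21 under SRα siRNA, where counting error alone gave 0.13 and 0.15. A ratio within 1.5-fold of equality was found for 91.5% of the 7703 genes under control siRNA and 91.3% under SRα siRNA. For the SRα ratios this share was 85.02% in the CBP80 IP and 87.4% in the eIF4E IP.

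**Figure D3:**
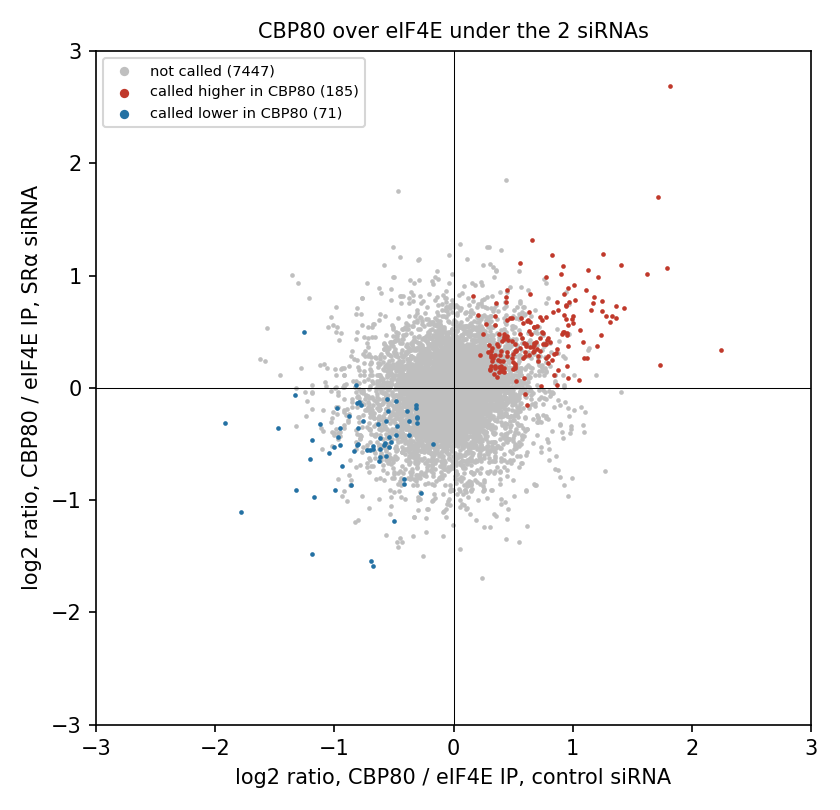
Log2 ratio of the CBP80 to the eIF4E IP under control siRNA (x axis) against that under SRα siRNA (y axis), with 1 point per measured gene, red for the 185 genes called higher in the CBP80 IP by the additive model, blue for the 71 called lower and grey for the rest. The cloud is rounder than that of the SRα ratios (Pearson correlation across genes 0.166 against 0.433), and 5 points, the IDs over 5 times higher in the SRα siRNA eIF4E library than in any other, lie beyond the axis limit of 3. Both correlations include these 5 IDs. Without them, among the 3064 genes with a mean of at least 100 counts, they were 0.421 and 0.721. Counting error was a larger part of the spread of the CBP80-to-eIF4E ratios there.

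The last comparison asked whether the SRα siRNA effect differed between CBP80-bound and eIF4E-bound RNA. By the 2-fold rule, the SRα effect was higher in the CBP80 than in the eIF4E IP for 79 genes, and draws with no effect gave 64.0 on average and up to 91. It was lower in the CBP80 IP for 105 genes, where the draws gave 61.3 on average and up to 89. At these settings the first count is within counting error and the second lies above it, and the second was 100 without the 5 IDs. The counts were 203 and 157 with no filter and 39 and 52 with a prior count of 5. With a mean of at least 100 counts they were 4 and 5. With 1 library per group the difference has no residual degrees of freedom, so no gene was tested for it.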

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

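The tests in this part were chosen after the counts were seen.

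For 3 gene IDs over 5 times higher in the SRα siRNA eIF4E library than in any other, the log2 ratio of SRα to control siRNA was above 0 in the eIF4E IP and below 0 in the CBP80 IP, where none of the 3 could be told from no change by its counting interval. The difference was not tested, as each group has 1 library. The first had 530 counts there against 10, 4 and 3 in the control CBP80, control eIF4E and SRα siRNA CBP80 libraries, a CBP80 IP ratio of 0.366 (0.0647 to 1.42), and a log2 ratio of SRα to control siRNA 8.74 higher in the eIF4E than in the CBP80 IP. The second had 197 counts against 19, 19 and 15, a CBP80 IP ratio of 0.963 (0.455 to 1.9996) and a difference of 3.95. The third had 102 against 13, 11 and 9, a CBP80 IP ratio of 0.844 (0.319 to 2.14) and a difference of 3.94. Read the other way, the log2 ratio of CBP80 to eIF4E was higher under control than under SRα siRNA by the same 8.74, 3.95 and 3.94. Their ratios to the next highest library were 59.6 (95% counting interval 32.1 to 125), 11.7 (7.26 to 19.8) and 8.82 (4.93 to 17.1).

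Together with ENSG00000124818.10 and ENSG00000201532.1 these make 5 IDs with at least 50 counts and over 5 times the level of any other library, all in the SRα siRNA eIF4E library, while 0 IDs met that rule in each of the other libraries. ENSG00000124818.10 was 445-fold above the next library, which had 2 counts (95% counting interval 123 to 3680). Counting error is argued against, since the highest number of IDs meeting this rule in any library was 0 in 1000 draws with no effect over all 7703 genes, though the rule was set after the IDs were seen. The draws treat reads as independent molecules, so they do not cover repeated reads of few molecules. The 5 IDs hold 0.177% of that library's gene counts, an amount that reads from another source in a single library could give. A response of eIF4E-bound RNA to SRα siRNA could give it too. With 1 library per group these cannot be told apart.

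The share of records placed at more than 1 position, which no comparison used, was above both control libraries (89.5% and 89.3%) in the SRα siRNA CBP80 library, at 90.7%, and in the SRα siRNA eIF4E library, at 90.3%. The sequences behind these records are not given in the files.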

How the results depend on the processing

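Leaving out the 5 IDs, thinning to equal totals and the robust fit were chosen after the data were seen, and the other alternatives before. Of 124 alternative values, 66 moved, meaning by over 1.5 times for a count or beyond a 95% interval over genes for a correlation, and 0 reversed. A count has no sign that could reverse, and the balance of higher and lower genes did turn in some settings. With no filter, SRα siRNA gave 275 higher and 210 lower genes in the CBP80 IP and 229 and 205 in the eIF4E IP. The difference between the SRα effects then gave 203 and 157. The CBP80-to-eIF4E comparisons kept more lower than higher genes there. For the named IDs, 2 of 24 log2 ratios left the counting interval of the reported value and 0 reversed, but that interval is wide for ENSG00000124818.10 in the CBP80 IP, where 0 and 2 counts gave 2.56 and, with a prior count of 5, 0.58. Counts are given as higher and lower in the order SRα in the CBP80 IP, SRα in the eIF4E IP, CBP80 against eIF4E under control siRNA, the same under SRα siRNA, and the difference between the SRα effects (107 and 135, 77 and 86, 44 and 49, 33 and 54, 79 and 105 as reported). Correlations are given for the SRα and then the IP effects (0.433 and 0.166), and additive calls likewise (1220 and 256).

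With a mean count of at least 100 they were 20 and 34, 10 and 20, 12 and 8, 4 and 4, and 4 and 5, the correlations 0.555 and 0.214, and the calls 751 and 107. There 3067 genes were tested and edgeR estimated 9.80 prior degrees of freedom, which were not separated. Of the calls that could still be tested, 727 of 813 for siRNA and 107 of 188 for the IP remained. With no filter the 2-fold counts were 275 and 210, 229 and 205, 119 and 193, 104 and 164, and 203 and 157, and the correlations were 0.0792 and 0.0226 as genes with few counts entered. With at least 10 counts, the counts were 185 and 185, 153 and 141, 76 and 124, 54 and 111, and 138 and 150. The correlations were 0.360 and 0.124. The calls were 806 and 137, and 774 of the 1220 remained. More genes were then tested (9530) and edgeR estimated 16.5 prior degrees of freedom in place of infinity, and these were not separated. With no filter, where the prior stayed infinite, 926 genes were called and 843 of the 1220 remained. With a prior count of 5, which shrinks ratios, the counts were 70 and 89, 49 and 57, 20 lower in the third comparison, 16 and 29, and 39 and 52, with correlations of 0.455 and 0.189. At 1.5-fold, a looser rule, they were 301 and 448, 319 and 391, 236 and 224, 128 and 170, and 177 and 243.

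With total counts, 75 genes were lower with CBP80 under control siRNA, and the median log2 ratio of that pair shifted by -0.06. DESeq2's Wald test called 106 and 32 genes, and the cause was not tested. After thinning, 20 genes were higher with CBP80 under SRα siRNA, and 749 and 121 genes were called, with 15.7 prior degrees of freedom. Without the 5 IDs the correlations were 0.475 and 0.207. The robust fit called 1220 and 256.

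No paired analysis was possible because the groups compared share fewer than 2 replicate numbers, although the additive model itself compares the siRNAs within each IP. Leaving out a library was not possible either, as each group has 1 and the additive model has 1 residual degree of freedom. The comparisons of ER client with cytosolic and nuclear gene lists, and their alternatives, were not run because the IDs were not matched to names, and pseudocounts for normalized values did not apply to counts. Depth limits the ratios most for the IP effect under SRα siRNA, where counting error alone gave a log2 SD of 0.15 at a mean of at least 100 counts against 0.21 observed.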

Other observations

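The tests against counting error in the SRα effects and against genes of high spread, the overlap within groups by mean count, the counts in ratios not used to choose the genes, and the cell-cycle lists were chosen after the data were seen.

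Genes that fell with SRα siRNA overlapped with genes that were higher in the CBP80 than in the eIF4E IP. Of the 611 and 185 genes called in the additive model, 69 were in both lists where 14.7 were expected from independent lists (odds ratio 7.65, 95% interval 5.52 to 10.5, across genes). Calls were more frequent among abundant genes, and within 10 equal groups by mean count 22.4 were expected (odds ratio 5.13, 3.72 to 7.07). On that basis, the genes that rose and were CBP80-higher numbered 21 where 26.6 were expected, those that rose and were CBP80-lower 9 where 6.69 were expected, and those that fell and were CBP80-lower 13 where 6.98 were expected. The 69 genes held 4.08% of the gene counts in the control CBP80 library, 2.99% in the control eIF4E library, 2.34% in the SRα siRNA CBP80 library and 1.85% in the SRα siRNA eIF4E library. Their median log2 ratio of SRα to control siRNA was -0.72 in the CBP80 IP and -0.47 in the eIF4E IP. Over the 3064 genes with a mean of at least 100 counts, the 2 effects had a Pearson correlation of -0.0251, inside the range of draws with no effect (-0.0991 to 0.0222). Their covariance of -0.00156 was below its range in the draws (-0.00105 to 0.000227). The draws hold counting error only, so the effects spread less in them, and neither range decides whether the 2 effects are linked.

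Among genes that the cell-cycle reference lists for G1, S and G2/M phase, 88, 102 and 90 were measured. With SRα siRNA 5, 10 and 3 of them rose and 8, 9 and 10 fell. In the CBP80 IP 4, 5 and 3 were higher than in the eIF4E IP and 0 were lower in each list. Of all 7703 measured genes, 609 rose and 611 fell with SRα siRNA, and 185 were CBP80-higher and 71 CBP80-lower. Whether the lists depart from these shares was not tested. The G1 list had a median log2 ratio of CBP80 to eIF4E of -0.04 under SRα siRNA, at percentile 1.37 of random lists of matched mean count, and of 0.05 under control siRNA, at percentile 70.7. The other medians of the 3 lists over the 4 comparisons lay between -0.07 and 0.06, at percentiles from 6.15 (G1, SRα in the CBP80 IP) to 91.1 (S, the same comparison), and 1 median, the first given, lay outside the central 95% of random lists.

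For the 69 genes, genes of high spread called in every direction remain open as a part of the overlap, since the highest odds ratio among the other pairs within groups by mean count was 2.11, with an interval (1.14 to 3.92) that meets that of 5.13. A control CBP80 library or an SRα siRNA eIF4E library that stands apart could give both calls, and neither is excluded. The medians without the library in question, 0.43 for the CBP80-to-eIF4E log2 ratio under SRα siRNA and -0.72 for the SRα log2 ratio in the CBP80 IP, pass the limits set beforehand, but the genes were called on averages that include these ratios, so the limits were too easy. Among 62 genes chosen for a change of at least 1.5-fold in both ratios that contain the control CBP80 library, the ratios without it had medians of -0.26 for SRα (77.4% lower, 65.0 to 87.1, quartiles -0.63 to -0.02) and 0.17 for CBP80 over eIF4E (67.7% higher, 54.7 to 79.1, quartiles -0.13 to 0.49), and among 31 chosen likewise for the SRα siRNA eIF4E library they were -0.32 (67.7% lower, 48.6 to 83.3, quartiles -0.67 to 0.16) and 0.23 (61.3% higher, 42.2 to 78.2, quartiles -0.16 to 0.53). These tested ratios still share libraries with the ratios that chose the genes, so an even split is not the chance value. Their intervals also treat genes as independent. A biological link between the 2 effects was not tested apart from the explanations above.

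The SRα effects were alike in both IPs, with a Pearson correlation of 0.721 across genes with a mean of at least 100 counts. Counting error is argued against, as the highest value in draws with no effect was 0.0723. Unequal gene count totals are argued against over all genes, where the correlation was 0.465 after thinning and 0.475 before, both without the 5 IDs. These values do not cover the abundant genes alone, and thinning does not remove repeated reads of few molecules. A culture, transfection or library batch shared by both IPs of 1 siRNA could give the same pattern and cannot be told apart from SRα depletion, since such a batch term coincides with siRNA and adds 0 to the rank of the model. SRα depletion therefore stays a hypothesis for the shared part, which had an SD of 0.29 on the log2 scale.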
